A study of Homo sapiens with 228 samples.

How the data were processed

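Messenger RNA was measured in 114 samples of human leukocytes in 22 groups, each sample on an HG-U133A and an HG-U133B Affymetrix array, 228 arrays in all. Groups held between 2 and 12 samples. The deposited values are linear MAS5 signal intensities per probe set, per the labels, and the labels give no MAS5 version and no scaling step. In the deposited tables the 2% trimmed mean over both chips of a sample, with shared probe sets counted once, was 500 in every sample, so the authors had scaled the 2 arrays of a sample together. The 168 probe sets on both chips (68 controls and 100 others) held 1 identical value in both tables and were left out of every test. The labels name no donor, batch or date.

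Because of the joint scaling, the trimmed mean of single arrays ran from 413.9 to 964.2 on HG-U133A and from 142.7 to 557 on HG-U133B. Each array was therefore multiplied to a common trimmed mean, 774.1 on HG-U133A and 265.1 on HG-U133B. The tests had been laid out on the assumption of a scaling per array, and this rescaling was chosen after the joint scaling was found, with the deposited scaling kept as an alternative. Values were used as log2(value + 16). This work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.

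Of 22283 probe sets on HG-U133A, 19065 had 1 gene symbol, 1043 had several and 2107 had none. On HG-U133B these were 15426, 554 and 6597 of 22645. Probe sets with several or no symbols were not used, nor were 31 and 21 sex-linked ones. A gene was taken from its brightest probe set on its chip, which gave 11899 genes on HG-U133A and 5554 that HG-U133B alone measures. A gene entered a comparison when at least as many arrays as the smallest group of its family held exceeded the chip median (324.6 and 161.7). That left 10188 genes in NK cells, 12096 in T cells, 14453 in B lineage cells, 11375 in monocytes and dendritic cells, and 15264 for the lineages.

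Groups were compared within 4 families (NK cells, T cells, B lineage, and monocytes with dendritic cells) with lmFit and eBayes(trend=TRUE) of limma, each chip on its own. The p-values are two-sided and Benjamini-Hochberg adjusted within a chip, and a gene passed at an adjusted p below 0.05. Lineages were compared across the 12 untreated groups, each lineage mean against the mean of the other 6. A lineage gene also had to lie at least 1 log2 unit above the highest other lineage mean. Gene lists written from general knowledge were tested with camera on the HG-U133A genes, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists run in that comparison. The number of list members past the test is given over all genes and adjusted over the list alone. The groups, comparisons, tests, lists and most alternatives were fixed before the data were examined.

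Named genes follow a rule. They come from those past the test whose samples do not overlap between the groups. The 6 largest rises and 6 largest falls on HG-U133A and the 3 and 3 largest on HG-U133B may be named, as may any member of that family's lists. For lineages these are the 6 and 3 widest margins and the list members. Not all genes the rule allows are printed. Genes present in only some people were not named, and immunoglobulin genes are named as uncertain because their probe sets share sequence. The 3 genes between the memory B cell classes are all named.

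The labels number the replicates, and whether a number marks a pair was tested by correlating, within each group, the deviations of like-numbered samples from their group mean. Every pair exceeded 0.1 on both chips for interleukin-15 against interleukin-2 (5 pairs), activated against unactivated memory CD4+ T cells (3) and LPS against untreated dendritic cells (6). The same held between the times for Th2 cells (3 pairs) but not for Th1 cells (2). All other numbers were read as shared by chance, and a replicate block was fitted to every comparison only as an alternative. Shared control groups were handled by simulating unchanged groups against the same controls 100 times and, where there were enough controls, by splitting them.

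The method was tested on simulated data with 200 changed genes per comparison. At a change of 2 log2 units, 78% were recovered for interleukin-2 in NK cells (76% at 1 and 98% at 3) and 92% for Th1 cells at 48 h (38% at 1). For the change of the Th2 and Th1 difference over time 54% were recovered at 2. False calls numbered 8 and 3 in the former comparisons. Many changes of 1 log2 unit could thus have been missed, and in the last comparison many of 2 as well.

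Alternatives were pseudocounts of 1 and 64, no filter, quantile normalization, eBayes without a trend, the mean of all probe sets of a gene, fits over all 22 groups or the compared groups only, the replicate block, a lineage margin of 2, and leaving out each replicate of groups of 2 to 5. Chosen after seeing the data were the deposited scaling, values floored at the chip median, the ACTB 3'/5' ratio as a covariate, Th2 numbers as pairs over the times, and exclusions of monocyte, T cell and naive B cell arrays. Splits of the samples were counted, at most 100 per comparison. A sample was marked as far from its group when its gap to the next sample exceeded Dixon's 95% critical value. Sequence-level data and raw scans were not analysed here.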

Results

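Messenger RNA levels were measured in 114 samples of human leukocytes, most of them isolated from peripheral blood mononuclear cells. Each sample was hybridised to 2 Affymetrix arrays, HG-U133A and HG-U133B, which held 11899 genes and a further 5554 genes. The T cell samples were resting CD8+ T cells (n = 4), resting CD4+ T cells (n = 3), and CD45RO+ memory CD4+ T cells before (n = 3) and after (n = 3) activation through CD3 and CD28. Other CD4+ T cells had been polarised to the Th1 state and restimulated through CD3 and CD28 for 12 h (n = 2) or 48 h (n = 3), or to the Th2 state and restimulated in the same way for 12 h (n = 3) or 48 h (n = 3). Natural killer (NK) cells were untreated (n = 4) or stimulated with interleukin-2 (n = 5) or interleukin-15 (n = 6). B lineage samples were naive B cells (n = 7), IgG/IgA memory B cells (n = 4), IgM memory B cells (n = 4), and plasma cells from blood (n = 3) and bone marrow (n = 4). Myeloid samples were monocytes at day 0 and after 1 or 7 days of macrophage differentiation in culture (n = 12 each). They also included CD14+ cell-derived dendritic cells without and with lipopolysaccharide (LPS) for 24 h (n = 6 each), and neutrophils (n = 5). Changes are differences of mean log2 signal ± SE. A gene is said to have risen or fallen only where it passed the limma test after adjustment. Since no label ties a sample to a donor or a culture, p-values measure only the spread between these samples.

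Across the 12 untreated groups, each lineage was set apart by genes at least 1 log2 unit above the highest other lineage. T cells (n = 10 samples over 3 groups) had 103 such genes. They were led by TRAT1, a T cell receptor adaptor, at 11.16 ± 0.84 (SD) against 6.48 in neutrophils. Others were UBASH3A (10.34 ± 0.39), the T cell receptor complex chains CD3D (14.33 ± 0.11) and CD3G (12.28 ± 0.16), and the costimulatory receptor ICOS (9.68 ± 1.03) and transcription factor LEF1 (13.47 ± 0.43). NK cells (n = 4) had 181, with the serine protease granzyme B gene GZMB at 14.44 ± 0.57 against 9.74 in T cells. The chemokine XCL1 stood at 12.96 ± 0.44, the lipid receptor S1PR5 at 9.94 ± 0.20 and the receptor KLRF1 at 13.73 ± 0.63. On HG-U133B these were joined by FGFBP2 at 13.29 ± 1.89 and the transcription factor EOMES at 12.66 ± 0.47. The widest NK margin belonged to LTF, which encodes the granulocyte granule protein lactoferrin, at 12.86 ± 0.95 against 7.18 in neutrophils. B cells (n = 15 samples over 3 groups) had 158, among them MS4A1, which encodes CD20, at 15.02 ± 0.30 against 9.60 in neutrophils. Others were BANK1 (13.21 ± 0.49), the transcription factor SPIB (12.20 ± 0.61), the chemokine receptor CXCR5 (10.02 ± 0.46), the cytokine IL7 (9.88 ± 0.56) and FCRL1 (11.05 ± 0.87).

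Plasma cells (n = 7 samples over 2 groups) had 311 lineage genes. The chaperone gene MZB1 stood at 15.24 ± 0.60 against 7.98 in B cells, a margin of 7.26. Also in this set were the survival receptor TNFRSF17 (14.07 ± 0.51), ITM2C (14.19 ± 0.21), the transcription factor BHLHA15 (11.39 ± 0.79) and the signal peptidase subunit SEC11C (14.33 ± 0.48). The immunoglobulin gene IGHA1 (11.63 ± 1.42) was another member, although probe sets of immunoglobulin genes share sequence and their identity is uncertain. Monocytes (n = 12) had 106, led by the proteoglycan VCAN at 14.97 ± 0.54 against 9.66 in neutrophils, with LGALS2 (12.09 ± 1.27), ASGR2 (11.17 ± 0.71), the scavenger receptor CD163 (12.45 ± 0.85) and SLC24A4 (10.03 ± 0.63). Dendritic cells (n = 6) had 396, with the complement genes C1QC at 13.73 ± 0.42 against 6.72 in monocytes and C1QB at 13.11 ± 0.81. Beside them stood the receptor TREM2 at 13.25 ± 0.50, A2M at 13.69 ± 0.49, NRP1 at 12.17 ± 0.27, the chemokine CCL17 at 12.07 ± 1.14 and the lipid-antigen-presenting molecule CD1B at 13.75 ± 0.91. Monocytes cultured towards macrophages were not among the lineages compared. C1QC and TREM2 also rose in those cultures by day 7 (below), so they do not mark dendritic cells alone. Neutrophils (n = 5) had 322, including the peptidase MME at 13.18 ± 0.26 against 7.88 in B cells. Also in this set were the chemokine receptors CXCR2 (14.15 ± 0.58) and CXCR1 (13.30 ± 0.62), FFAR2 (12.36 ± 0.92), the Fc receptor FCGR3B (15.64 ± 0.40) and CMTM2 (14.47 ± 0.33).

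Among the marker lists, 10 of 14 measured T cell genes, 11 of 12 NK cell genes, and 13 of 18 B cell genes were lineage genes of the cell type they stand for. The same held for 13 of 16 plasma cell genes, 9 of 14 dendritic cell genes and 16 of 16 neutrophil genes. Of the 14 monocyte list genes only 3 were monocyte lineage genes, while 6 were neutrophil lineage genes. In 86 of 114 samples on HG-U133A and 82 of 114 on HG-U133B the nearest other sample belonged to the same group.

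**Figure D1:**
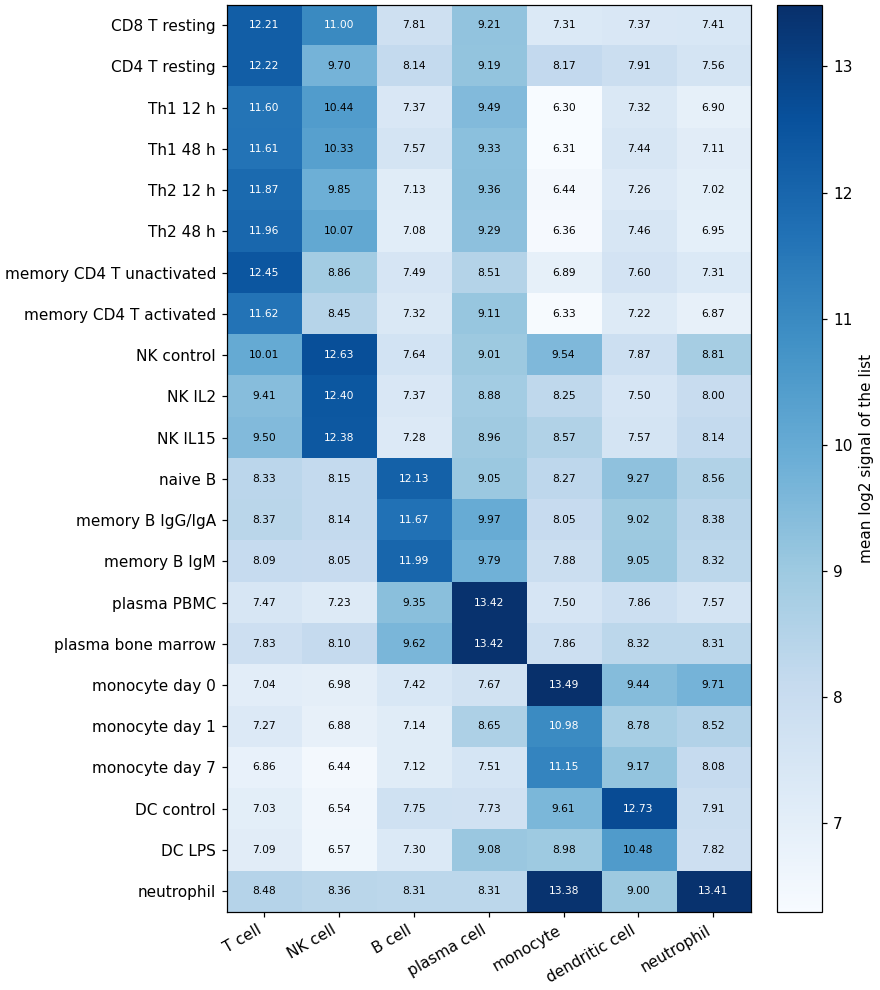
Mean log2 signal of 7 marker lists (columns) in the 22 groups (rows), with the group mean printed in each cell and darker shading for higher values. The NK cell list stands at 12.63 in untreated NK cells and the neutrophil list at 13.41 in neutrophils.

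After interleukin-2 stimulation of NK cells (n = 5 against 4 untreated) the lymphotoxin gene LTA rose by 5.89 ± 0.61 (adjusted p = 3.44e-05) and the cytokine genes LIF and OSM by 4.33 ± 0.66 and 3.42 ± 0.50. The interleukin-2 receptor alpha chain gene IL2RA rose by 3.77 ± 0.81, and the replication factors CDC45 and GINS2 by 4.19 ± 0.30 and 3.79 ± 0.56. On HG-U133B, NDFIP2 rose by 3.30 ± 0.22, UHRF1, a maintenance factor of DNA methylation, by 2.95 ± 0.54 and ZNF367 by 2.58 ± 0.37. The genes that fell most included CAMP, a granulocyte antimicrobial peptide, which fell by 4.50 ± 1.05, and DPEP2 (-4.35 ± 0.71). The receptor kinase EPHA4 (-3.65 ± 0.76), the granule gene LCN2 (-2.98 ± 0.66), the phosphatase DUSP1 (-2.91 ± 0.53) and the granzyme gene GZMK (-2.70 ± 0.40) fell too. In all, 611 genes rose and 349 fell.

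Of 26 measured cell cycle genes, 15 rose and 0 fell (18 rose when adjusted over the list alone), with the replication helicase genes MCM4 at 2.80 and MCM2 at 2.66. The camera set test gave adjusted p = 6.82e-14, and adjusted p = 0.0884 with an estimated correlation. Cholesterol synthesis had 7 of 13 genes higher, among them SQLE at 1.66 and DHCR7 at 1.20 (10 adjusted over the list alone). Glycolysis had 6 of 18, among them PKM at 2.33 and ENO1 at 1.01 (7 adjusted over the list alone). Both sets passed with either correlation (adjusted p = 7.54e-06 and 0.000256, and adjusted p = 0.0245 for each with an estimated correlation). Of 16 lymphocyte activation genes 9 rose (12 rose and 1 fell adjusted over the list alone), including the costimulatory receptor TNFRSF18 at 2.55, with adjusted p = 4.42e-06 and adjusted p = 0.241 with an estimated correlation. Among 33 genes of the endoplasmic reticulum and unfolded protein response 4 rose, such as MANF at 1.48 (7 adjusted over the list alone; adjusted p = 1.64e-05, and adjusted p = 0.373 with an estimated correlation). In the granulocyte precursor list 6 of 10 genes fell (10 adjusted over the list alone), with a median of -2.63, adjusted p = 3.68e-06 and adjusted p = 0.241 with an estimated correlation. The mean level of this list was 10.50 ± 1.25 (SD) in untreated NK cells, 7.93 ± 0.67 after interleukin-2 and 8.40 ± 1.37 after interleukin-15, beside 8.61 ± 0.40 in neutrophils. The cytotoxic granule list held 0 genes that rose and 1 that fell, GZMK, of 16 measured (adjusted p = 0.679), and 0 of 22 interferon response genes changed. The median of the latter list was -0.11 (adjusted p = 0.679), but 0.62 (adjusted p = 0.0328) without untreated replicate 3 and -0.66 (adjusted p = 0.0346) without interleukin-2 replicate 4, and over 20 alternatives its adjusted p ranged up to 0.913. The count of genes fell to 587 and 546 without untreated replicates 1 and 2 and rose to 1454 without untreated replicate 3. Under the deposited scaling 75.5% of the changed genes rose, against 63.6% here.

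**Figure D2:**
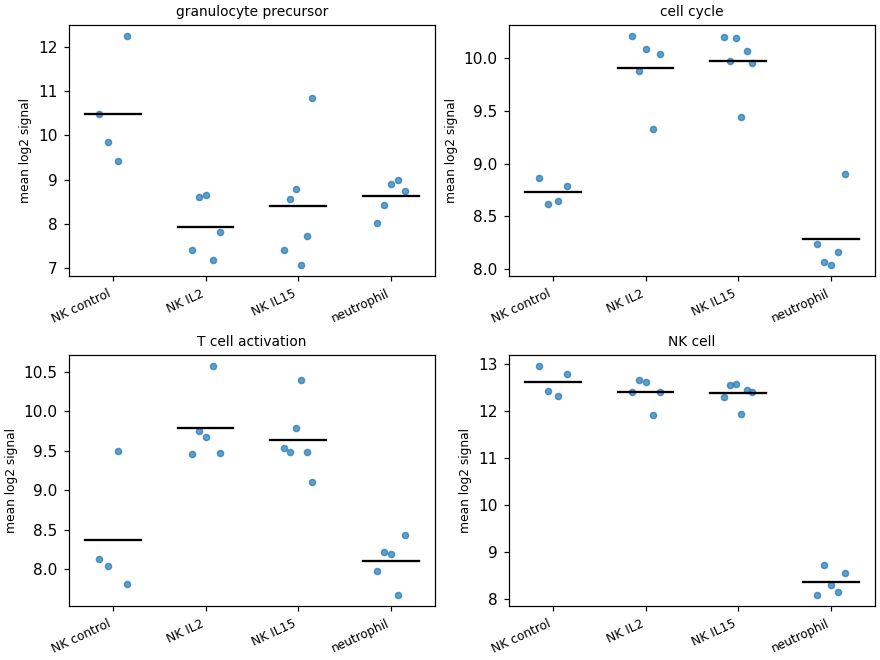
Mean log2 signal of 4 gene lists in each NK and neutrophil sample, with points for samples and bars for group means. The granulocyte precursor list spans 9.41 to 12.25 in untreated NK cells and 7.18 to 8.65 after interleukin-2.

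Interleukin-15 (n = 6 against 4) raised 833 genes and lowered 426. LTA rose by 6.13 ± 0.58, LIF by 4.04 ± 0.64, CDC45 by 4.15 ± 0.29, the growth factor gene HBEGF by 3.82 ± 0.57 and the lymphotoxin beta gene LTB by 3.75 ± 0.36. Among genes that fell were DPEP2 (-4.31 ± 0.69), EPHA4 (-3.30 ± 0.73), the chloride channel gene CLIC3 (-2.78 ± 0.68) and the chemokine receptor CXCR4 (-2.48 ± 0.49). Cell cycle genes rose at 18 of 26 (19 adjusted over the list alone; adjusted p = 8.35e-15, and adjusted p = 0.075 with an estimated correlation). Glycolysis rose at 9 of 18 (11 adjusted over the list alone; adjusted p = 3.43e-05 and 0.0147 with an estimated correlation). Cholesterol synthesis rose at 9 of 13 (10 rose and 2 fell adjusted over the list alone; adjusted p = 1.96e-05 and 0.0324 with an estimated correlation). The endoplasmic reticulum list rose at 9 of 33 (14 adjusted over the list alone; adjusted p = 6.5e-06, and adjusted p = 0.344 with an estimated correlation). In the granulocyte precursor list 4 of 10 genes fell, including CTSG at -2.05 (9 adjusted over the list alone; adjusted p = 8.23e-05, and adjusted p = 0.344 with an estimated correlation). Without untreated replicates 1 and 2 the count of 1259 genes became 807 and 703, and under the deposited scaling 84.9% of the changed genes rose, against 66.2% here.

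The 2 cytokines were compared directly in 6 and 5 samples. In limma 0 genes passed, with 130 at an unadjusted p under 0.05, and the numbered pairs gave 0 as well. The widest list shift was that of the granulocyte precursor genes, with a median of 0.52 in favour of interleukin-15 (adjusted p = 0.0257, and adjusted p = 0.978 with an estimated correlation). It did not pass without interleukin-2 replicates 1, 4 or 5 (adjusted p = 0.196, 0.141 and 0.0635), with the mean of all probe sets (adjusted p = 0.0709) or under the deposited scaling (adjusted p = 0.106), and with the numbered pairs as a block its median was -0.04 (adjusted p = 0.872, where the 16 alternatives began at 1.23e-05). The oxidative phosphorylation genes had a median of 0.11 (adjusted p = 0.00168, and adjusted p = 0.511 with an estimated correlation) and did not pass without interleukin-2 replicate 2 (adjusted p = 0.0719) or with the mean of all probe sets (adjusted p = 0.0709), where the alternatives began at 0.000284. Against the shared untreated samples the changes after the 2 cytokines correlated at 0.93 across 10188 genes, where unchanged groups simulated against those samples gave 0.58. The covariance was 0.323 beside a simulated 0.064. After both cytokines 570 genes rose and 252 fell, where independent lists would share 50 and 14.6. With the untreated samples split between the comparisons the correlation was 0.71, with 178 genes higher and 25 lower after both. None of these no-change values allows for the numbered pairs that the 2 cytokine groups share.

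Restimulated Th1 cells at 48 h (n = 3) differed from resting CD4+ T cells (n = 3) in 2232 genes that rose and 1951 that fell. The mitotic spindle gene ASPM rose by 7.20 ± 0.66 (adjusted p = 2.85e-08), GINS2 by 6.15 ± 0.41 and the topoisomerase gene TOP2A by 5.56 ± 0.52. The effector cytokine gene IFNG rose by 5.92 ± 0.36, ZBED2 by 5.69 ± 0.68 and the fatty acid transporter gene SLC27A2 by 5.62 ± 0.43. On HG-U133B the largest rises were JAKMIP1 (5.01 ± 0.47) and LINC01943 (4.38 ± 0.61). The array of resting replicate 1 stood apart on that chip, and without it 4594 genes changed in place of 4183. The genes that fell most were LYZ (-7.18 ± 0.99) and S100A8 (-5.37 ± 0.67), which monocytes and granulocytes express, and DPEP2 (-5.52 ± 0.62). DUSP1 (-4.85 ± 0.41), APBA2 (-4.83 ± 0.48) and, on HG-U133B, NOG, an inhibitor of bone morphogenetic proteins (-5.15 ± 0.46), fell as well. The monocyte marker list stood at 8.17 ± 0.63 (SD) in resting CD4+ T cells, against 6.89 ± 0.14 in unactivated memory CD4+ T cells.

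Every one of the 29 measured cell cycle genes rose in Th1 cells at 48 h (29 adjusted over the list alone), with a median of 3.42. They included the mitotic kinase AURKA at 4.67 and the transcription factor FOXM1 at 5.01 (adjusted p = 1.33e-25, and adjusted p = 0.0773 with an estimated correlation). All 14 T cell quiescence genes fell, such as TXNIP at -4.48, PIK3IP1 at -4.21 and the lymph node homing receptor CCR7 at -1.97 (14 adjusted over the list alone; adjusted p = 5.95e-09, and adjusted p = 0.0569 with an estimated correlation). Of 14 Th1 genes 10 rose (10 adjusted over the list alone), including GZMB at 4.38 and the interleukin-12 receptor chain IL12RB2 at 3.36 (adjusted p = 0.00109, and adjusted p = 0.187 with an estimated correlation). Of 12 Th2 genes 0 rose and 1 fell, the receptor PTGDR2 at -2.08. Glycolysis rose at 13 of 18 (13 adjusted over the list alone; adjusted p = 9.54e-06, and adjusted p = 0.198 with an estimated correlation). Oxidative phosphorylation rose at 16 of 23, with COX4I1 lower at -0.78 (18 rose and 2 fell adjusted over the list alone; adjusted p = 0.000113, and adjusted p = 0.248 with an estimated correlation). Immediate early genes fell at 6 of 11, with FOS at -4.73 (1 rose and 7 fell adjusted over the list alone; adjusted p = 0.00875, and adjusted p = 0.333 with an estimated correlation).

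Th2 cells at 48 h (n = 3) against the same resting cells had 2041 genes higher and 1894 lower, and without the HG-U133B array of resting replicate 1 the count of 3935 became 4367. ASPM rose by 7.16 ± 0.66, the neuropeptide gene PMCH by 5.83 ± 0.54, CEP55 by 5.25 ± 0.57 and EOMES by 4.35 ± 0.34. FOS (-6.17 ± 0.74), DUSP1 (-5.49 ± 0.41), SCML1 (-5.21 ± 0.48) and the integrin gene ITGA6 (-5.01 ± 0.61) fell. All 29 cell cycle genes rose here too (adjusted p = 6.91e-26, and adjusted p = 0.0746 with an estimated correlation). Of the quiescence genes 13 of 14 fell (14 adjusted over the list alone), among them the interleukin-7 receptor IL7R at -4.62, with adjusted p = 6.84e-10 and 0.0383 with an estimated correlation. Th2 genes rose at 6 of 12, with the interleukin-25 receptor IL17RB at 4.51 and the cytokines IL5 at 3.40, IL4 at 3.17 and IL13 at 2.85 (6 adjusted over the list alone; adjusted p = 0.0213, and adjusted p = 0.254 with an estimated correlation). Th1 genes rose at 5 of 14, with IFNG at 3.70 and the chemokine CCL4 at 3.51 (5 adjusted over the list alone; adjusted p = 0.0274, and adjusted p = 0.254 with an estimated correlation). The Th1 set, with a median of 0.77, did not pass without resting replicate 2 (0.55, adjusted p = 0.163) or with values floored at the chip median (0.23, adjusted p = 0.0723), where the 18 alternatives began at 0.00309. Both polarised states raised 1729 genes and lowered 1420, where independent lists would share 376.6 and 305.5. Their changes correlated at 0.91 (0.50 for simulated unchanged groups) with a covariance of 0.990 beside a simulated 0.076. The 3 resting samples are too few to split between the comparisons.

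Th2 and Th1 cells were then compared with each other. At 12 h (n = 3 and 2) 7 genes were higher in Th2 cells and 0 lower. They were IL13, a Th2 cytokine, at 3.15 ± 0.53 (adjusted p = 0.0185), the arginase gene ARG2 at 2.15 ± 0.37, DENND5A at 2.02 ± 0.35 and the phosphatase gene INPP4B at 1.62 ± 0.29. The other 3, on HG-U133B, were C1orf162 at 3.66 ± 0.56, ZNF488 at 3.37 ± 0.57 and BMS1P1 at 1.92 ± 0.29. At 48 h (n = 3 and 3) 18 genes were higher and 5 lower. The former included PTPN20 at 4.14 ± 0.83, IL17RB at 3.75 ± 0.66, IL5 at 3.42 ± 0.68, the prolyl hydroxylase gene EGLN3 at 3.22 ± 0.50 and FILIP1L at 2.99 ± 0.51. The latter were IL12RB2 at -3.12 ± 0.65 (adjusted p = 0.0395), IFNG at -2.22 ± 0.36, RGS16 at -2.13 ± 0.41, NCALD at -1.34 ± 0.23 and GAS7 at -1.34 ± 0.26.

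The Th2 gene list was higher in Th2 cells at 12 h, with 1 of 12 genes past the test and 5 adjusted over the list alone (median 0.89, adjusted p = 1.79e-07, and adjusted p = 0.0799 with an estimated correlation). At 48 h it was higher too, with 2 past it and 6 adjusted over the list alone (median 1.35, adjusted p = 1.16e-06, and adjusted p = 0.119 with an estimated correlation). The Th1 list was lower, with a median of -0.47 at 12 h (0 of 14, and 3 adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.385 with an estimated correlation). Its median was -0.63 at 48 h (2 of 14, and 2 adjusted over the list alone; adjusted p = 0.000666, and adjusted p = 0.189 with an estimated correlation). At 12 h the Th2 set did not pass without Th1 replicate 2 (adjusted p = 0.0622), nor the Th1 set without Th1 replicate 1 (adjusted p = 0.173), where the 17 alternatives began at 1.24e-11 and 0.000385. The difference between Th2 and Th1 cells was not shown to change between the times. In that comparison 0 genes passed the interaction test in limma, with 210 at an unadjusted p under 0.05. At 12 h the 7 genes became 2 and 3 without Th2 replicates 1 and 2 and 1 without Th1 replicate 2. A fit on the compared groups alone gave 0 genes at 12 h and 6 at 48 h. At 48 h the 23 became 15, 37 and 8 without Th2 replicates 1, 2 and 3 and 13, 40 and 14 without Th1 replicates 1, 2 and 3. The deposited scaling gave 91.5% of the 48 h genes higher in Th2 cells, against 78.3% here.

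**Figure D3:**
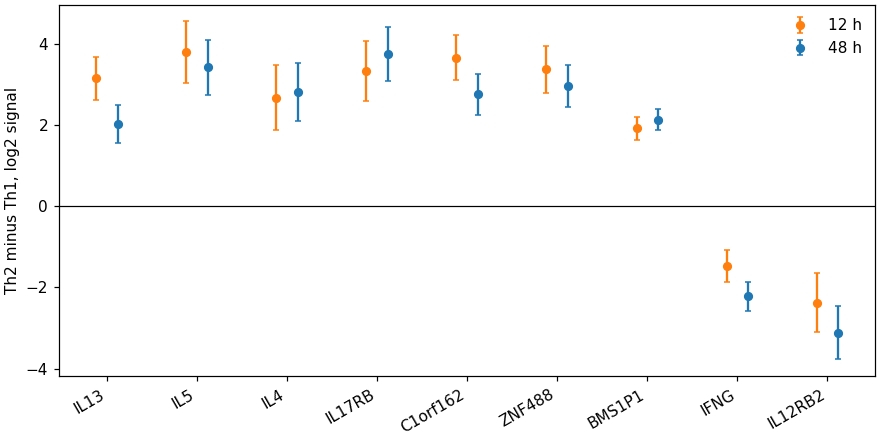
Difference of mean log2 signal between Th2 and Th1 cells at 12 h and 48 h for 9 genes, with bars for the SE of the difference and a line at 0. IL5 stands at 3.42 and IFNG at -2.22 at 48 h.

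From 12 h to 48 h, averaged over Th1 and Th2 cells, 337 genes rose and 397 fell. The mitotic genes CDCA8 (2.54 ± 0.42, adjusted p = 0.000749), ASPM (2.46 ± 0.49), PLK1 (2.25 ± 0.32), HMMR (2.21 ± 0.23) and KIF20A (2.12 ± 0.42) rose most. The tumour necrosis factor family ligand TNFSF14 (-1.98 ± 0.43), TNIP3 (-1.89 ± 0.45), PHLDA2 (-1.85 ± 0.30) and the gap junction gene GJB2 (-2.50 ± 0.55) fell. Cell cycle genes rose at 16 of 29 (18 adjusted over the list alone; adjusted p = 1.39e-13, and adjusted p = 0.272 with an estimated correlation). MHC class II genes rose at 3 of 10, with HLA-DRA at 1.78 (5 adjusted over the list alone; adjusted p = 0.00179, and adjusted p = 0.272 with an estimated correlation). Activation genes fell at 5 of 20, with LTA at -3.56 and MYC at -1.73 (8 adjusted over the list alone; adjusted p = 0.000236, and adjusted p = 0.17 with an estimated correlation). Th2 genes fell at 4 of 12, with IL5 at -3.31 and IL10 at -2.40 (6 adjusted over the list alone; adjusted p = 0.00069, and adjusted p = 0.272 with an estimated correlation). The 734 genes became 439 without Th1 48 h replicate 3, 236 without Th1 12 h replicate 1 and 385 without Th2 12 h replicate 2, and 890 with the Th2 samples paired by number.

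Activation of CD45RO+ memory CD4+ T cells (n = 3 and 3) raised 1913 genes and lowered 1778. GZMB rose by 7.13 ± 0.58 (adjusted p = 1.41e-08), the growth factor gene IL3 by 6.90 ± 1.12, and ZBED2 by 6.62 ± 0.68. Next came CCL4 by 6.55 ± 0.75, LTA by 6.25 ± 1.03 and EVI5 by 5.48 ± 0.71, with UHRF1 (6.45 ± 0.90) and CDCA5 (5.62 ± 0.92) on HG-U133B. KLF2, a transcription factor of resting T cells, fell by 5.38 ± 0.47, DPEP2 by 5.07 ± 0.62, and LY9 by 5.03 ± 0.62. Smaller falls were those of DUSP1 by 4.90 ± 0.41, FOS by 4.87 ± 0.74 and the glucocorticoid-induced gene TSC22D3 by 4.46 ± 0.33. All 29 cell cycle genes rose (median 3.14, adjusted p = 2e-26, and adjusted p = 0.0698 with an estimated correlation). Activation genes rose at 15 of 20, with IRF4 at 3.92, while CD69 fell by 1.96 (15 rose and 1 fell adjusted over the list alone; adjusted p = 4.27e-06, and adjusted p = 0.05 with an estimated correlation). Th1 genes rose at 8 of 14, with IFNG at 5.05 and STAT4 lower at -0.69 (9 rose and 1 fell adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.241 with an estimated correlation). Quiescence genes fell at 9 of 14 while the chromatin organiser SATB1 rose by 0.82 (1 rose and 9 fell adjusted over the list alone; adjusted p = 0.000164, and adjusted p = 0.204 with an estimated correlation). Memory T genes fell at 5 of 18, such as the lectin receptor KLRB1 at -3.85 (1 rose and 5 fell adjusted over the list alone; adjusted p = 0.134). With the numbered pairs as a block this set passed (adjusted p = 0.028, where the 18 alternatives ran from 0.0219 to 0.237), and 5025 genes changed in place of 3691. The cytotoxic granule list went both ways, with 4 of 16 higher and 3 lower, among them GZMK at -3.99 (median -0.47, mean -0.08 and a camera direction of up, adjusted p = 0.992).

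Before activation, memory CD4+ T cells (n = 3) differed from resting CD4+ T cells (n = 3) in 374 genes that were higher and 248 that were lower. Higher were the fucosyltransferase gene FUT7 (3.40 ± 0.59, adjusted p = 0.00325), CHN1 (2.85 ± 0.51) and the chemokine receptors CCR6 (2.83 ± 0.74) and CCR2 (2.53 ± 0.48). So were the transcription factor MAF (2.65 ± 0.54) and, on HG-U133B, TMEFF2 (3.54 ± 0.33). Lower were JCHAIN (-5.07 ± 1.15) and the immunoglobulin light chain gene IGLC1 (-3.98 ± 0.96, identity uncertain), which B lineage cells express. Lower too were AIF1 (-4.11 ± 0.86) and S100A8 (-3.71 ± 0.67), which monocytes express, and DSC1 (-3.65 ± 0.54) and TAOK1 (-3.45 ± 0.62). The B cell and monocyte marker lists stood at 8.14 ± 0.31 and 8.17 ± 0.63 (SD) in resting CD4+ T cells and at 7.49 ± 0.18 and 6.89 ± 0.14 in memory cells. Memory T genes were higher at 7 of 18, with CD58 at 1.93 and FAS at 1.76 (12 adjusted over the list alone; adjusted p = 6.48e-12, and adjusted p = 0.123 with an estimated correlation). MHC class II genes were lower at 2 of 10, with HLA-DRA at -2.75 (5 adjusted over the list alone; adjusted p = 0.00126, and adjusted p = 0.4 with an estimated correlation). This set did not pass without resting replicate 3 (adjusted p = 0.0527, where the 18 alternatives began at 4.75e-06). Quiescence genes were lower at 2 of 14, SATB1 at -1.14 and BACH2 at -1.38 (2 adjusted over the list alone; adjusted p = 0.00367, and adjusted p = 0.4 with an estimated correlation). The 622 genes became 393, 258 and 357 without memory replicates 1, 2 and 3 and 351 without resting replicate 2, but 900 without resting replicate 1. Of the 622, 336 lie on HG-U133B, where the array of resting replicate 1 stood apart, and leaving out that array gave 902. The deposited scaling gave 42.4% of them higher, against 60.1% here.

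CD8+ T cells (n = 4) against CD4+ T cells (n = 3), both at rest, differed most in their coreceptors. CD8A was higher by 6.32 ± 0.40 (adjusted p = 1.18e-09) and CD8B by 5.36 ± 0.38, and CD4 fell by 4.20 ± 0.56. The adhesion molecule CRTAM (3.06 ± 0.43), TNFSF14 (2.41 ± 0.54), GZMK (2.32 ± 0.52) and the inhibitory receptor KLRG1 (2.14 ± 0.38) were also higher, as were, on HG-U133B, GAB3 (3.34 ± 0.56), TTC16 (3.27 ± 0.49) and EOMES (3.17 ± 0.32). The coagulation factor gene F5 (-2.61 ± 0.47), ANKRD55 (-2.46 ± 0.48) and TIAM1 (-2.11 ± 0.28) were lower. In all 212 genes were higher and 67 lower. The CD8 T list was higher at 7 of 13 (12 adjusted over the list alone), with adjusted p = 6.5e-19 and 0.00722 with an estimated correlation. The cytotoxic granule list was higher at 3 of 16, with GZMA at 1.81 and UNC13D at 1.65 (8 adjusted over the list alone; adjusted p = 8.39e-05, and adjusted p = 0.332 with an estimated correlation). It did not pass without CD4+ replicate 2 (adjusted p = 0.0627, where the 19 alternatives began at 8.18e-10), and the TNFSF14 difference was 0 with values floored at the chip median. Beside these groups, the NK cell list ranged from 7.89 to 11.07 over the 3 resting CD4+ samples and stood at 11.00 ± 0.52 (SD) in CD8+ cells. Resting CD4+ replicate 1 stood apart on HG-U133B: leaving that array out gave 502 genes, and leaving out the whole sample 571. Of the 279 genes, 176 lie on HG-U133B and 103 on HG-U133A. On HG-U133B all pairs of resting CD4+ samples correlated weakly, at 0.732 to 0.786, against 0.886 to 0.922 between CD8+ samples. The 279 genes became 146 without CD4+ replicate 2 and 161, 178 and 163 without CD8+ replicates 2, 3 and 4. Of the changed genes 57.1% were higher under the deposited scaling, against 76.0% here.

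IgG/IgA memory B cells (n = 4) compared with naive B cells (n = 7) had 289 genes higher and 116 lower. The lectin gene LGALS1 was higher by 5.00 ± 0.40 (adjusted p = 6.65e-09), CRIP1 by 4.03 ± 0.58 and BAIAP3 by 3.55 ± 0.56. Also higher were MCM6 by 3.34 ± 0.50, COCH by 3.21 ± 0.25 and the repressor ZBTB32 by 3.19 ± 0.48, with PAG1 (3.15 ± 0.60) on HG-U133B. TCL1A, a kinase coactivator of naive B cells, changed by -3.52 ± 0.23, IGHM, the IgM heavy chain (identity uncertain), by -2.92 ± 0.21. Also lower were YBX3 at -2.84 ± 0.21, IL21R at -2.84 ± 0.43 and IL4R at -2.28 ± 0.25, with MACROD2 (-3.54 ± 0.36) on HG-U133B. The memory B list was higher at 9 of 15, with AIM2 at 2.93 and CD27 at 2.46 (10 adjusted over the list alone; adjusted p = 1.06e-15 and 0.00144 with an estimated correlation). The naive B list was lower at 9 of 12, with BACH2 at -1.41 and FCER2 at -1.86 (11 adjusted over the list alone; adjusted p = 9.34e-21 and 0.000101 with an estimated correlation). Oxidative phosphorylation was higher at 8 of 23 (12 adjusted over the list alone; adjusted p = 2.26e-13, and adjusted p = 0.0888 with an estimated correlation). The plasma cell list was higher at 4 of 16, with TNFRSF17 at 2.92 and JCHAIN at 2.58 (6 adjusted over the list alone; adjusted p = 5.68e-06, and adjusted p = 0.069 with an estimated correlation). The 405 genes became 180 and 245 without memory replicates 1 and 2. Naive replicate 6 stood apart from its group, and without it 882 genes differed.

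In IgM memory B cells (n = 4) 202 genes were higher than in naive cells and 77 lower. LGALS1 was higher by 5.15 ± 0.40, TNS3 by 3.70 ± 0.50, CRIP1 by 3.56 ± 0.58, EHD3 by 2.91 ± 0.35 and CSGALNACT1 by 2.87 ± 0.33. The genes IL21R (-3.35 ± 0.43), TCL1A (-2.89 ± 0.23), IL4R (-2.50 ± 0.25), CD9 (-2.52 ± 0.59) and MACROD2 (-3.29 ± 0.36) were lower. The memory B list was higher at 6 of 15, with CD27 at 2.58 (8 adjusted over the list alone; adjusted p = 3.27e-12 and 0.00504 with an estimated correlation). The naive B list was lower at 6 of 12 (10 adjusted over the list alone; adjusted p = 1.2e-16 and 0.000386 with an estimated correlation). Against the shared naive samples 146 genes were higher and 45 lower in both memory classes, where independent lists would share 4 and 0.6. The correlation was 0.65 (simulated 0.36), the covariance 0.140 (simulated 0.048), and with the naive samples split the correlation was 0.39 with 40 genes higher and 20 lower. Set against each other, the memory classes differed in 3 genes: IgG/IgA cells had more COCH (2.03 ± 0.28, adjusted p = 0.000679), less IGHM (-2.88 ± 0.24) and less LINC01857 (-1.50 ± 0.25). Without IgM replicates 1, 2 and 4 the 279 genes became 136, 124 and 136, and without naive replicate 6 they became 684. The 3 genes became 5 and 7 without IgG/IgA replicates 1 and 3 and 7 without IgM replicate 1.

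Plasma cells from blood (n = 3) were far from naive B cells (n = 7), with 2567 genes higher and 4923 lower. The secretory chaperone genes MZB1 and HSP90B1 were higher by 7.68 ± 0.61 (adjusted p = 3.2e-10) and 7.51 ± 0.69. LGALS1 was higher by 7.58 ± 0.44, TNFRSF17 by 7.39 ± 0.74, the surface receptor SLAMF7 by 6.44 ± 0.48 and MANF by 6.22 ± 0.70, beside SEC11C (4.94 ± 0.35) and SELENOS (4.76 ± 0.26) on HG-U133B. The B cell surface molecule gene MS4A1 changed by -5.95 ± 0.22, IL4R by -5.94 ± 0.28, LTB by -5.78 ± 0.23, GPR18 by -5.32 ± 0.39 and TCL1A by -5.16 ± 0.26. Of 33 endoplasmic reticulum and unfolded protein response genes 30 were higher, with SEC61A1 at 5.25, and 2 lower (30 and 2 adjusted over the list alone; adjusted p = 2.67e-23 and 0.01 with an estimated correlation). The lower genes were DDIT3 at -0.79 and the stress sensor ERN1 at -0.94. All 16 plasma cell genes were higher, with CD38 at 5.04 and IRF4 at 1.24 (16 adjusted over the list alone; adjusted p = 1.3e-15 and 0.00272 with an estimated correlation). The 23 oxidative phosphorylation genes were all higher (23 adjusted over the list alone; adjusted p = 1.41e-16 and 0.0398 with an estimated correlation), with UQCRC1 at 4.24. The B cell list was lower at 16 of 18, with POU2AF1 higher at 1.66 (2 higher and 16 lower adjusted over the list alone; adjusted p = 1.08e-06 and 0.0354 with an estimated correlation). The naive B list was lower at 12 of 12 (12 adjusted over the list alone; adjusted p = 8.44e-08 and 0.01 with an estimated correlation) and the MHC class II list at 9 of 10, with HLA-DMB at -3.62 (9 adjusted over the list alone; adjusted p = 0.000246 and 0.0354 with an estimated correlation). Cell cycle genes were higher at 19 of 28, with TOP2A at 3.98 (19 adjusted over the list alone; adjusted p = 9.45e-08, and adjusted p = 0.0952 with an estimated correlation). The median of all genes was -0.38 here and -0.13 after quantile normalization, which gave 46.2% of changed genes higher, against 34.3% here. The median array signal was 310 ± 21.6 (SD) in blood plasma cells and 516 ± 68.5 in naive B cells.

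**Figure D4:**
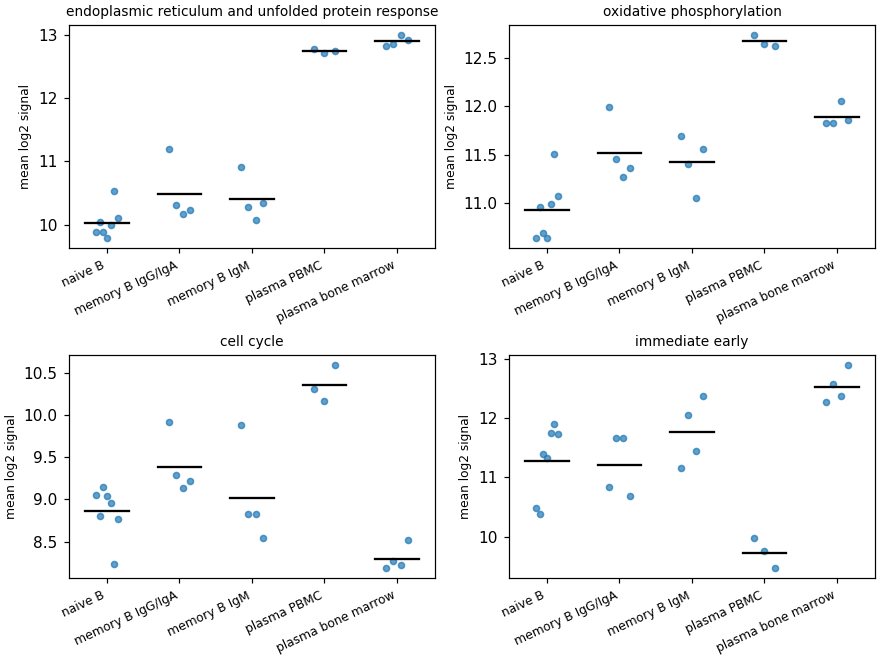
Mean log2 signal of 4 gene lists in each B cell and plasma cell sample, with points for samples and bars for group means. All 23 oxidative phosphorylation genes were higher in blood plasma cells than in naive B cells.

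Bone marrow plasma cells (n = 4) differed from those of blood (n = 3) in 1906 genes that were higher and 1486 that were lower. The immediate early genes FOSB (6.24 ± 0.85, adjusted p = 1.07e-05), FOS (4.78 ± 0.85) and KLF6 (4.76 ± 0.34) were higher. So were the small heat shock protein gene HSPB1 (5.11 ± 0.65), DNAAF1 (4.58 ± 0.49), PLTP (4.19 ± 0.58) and CTHRC1 (3.47 ± 0.33). CD52 changed by -5.18 ± 0.36, HLA-DRA by -5.10 ± 0.36, the histone chaperone gene NASP by -4.58 ± 0.77, ASPM by -4.35 ± 0.71 and the spindle motor gene KIF11 by -4.08 ± 0.57. Cell cycle genes were lower at 24 of 28 (25 adjusted over the list alone; adjusted p = 3.16e-18 and 0.0456 with an estimated correlation), with PCNA at -3.62. Immediate early genes were higher at 9 of 11 (10 adjusted over the list alone; adjusted p = 2.7e-07, and adjusted p = 0.12 with an estimated correlation). Oxidative phosphorylation was lower at 12 of 23 (17 adjusted over the list alone; adjusted p = 1.35e-09, and adjusted p = 0.304 with an estimated correlation). Of 16 plasma cell genes SDC1, which encodes CD138, was higher at 1.44, and IRF4 and PIM2 were lower at -1.26 and -1.37 (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.466). The erythroid list, with HBB higher at 1.32, stood at 8.29 ± 0.05 (SD) in marrow and 7.35 ± 0.22 in blood (2 of 4 higher, and 3 adjusted over the list alone; adjusted p = 0.315). The median of all genes was 0.23, and 0.07 after quantile normalization, under which 40.0% of changed genes were higher, against 56.2% here and 68.5% under the deposited scaling. The 3392 genes became 2167 and 1964 without blood replicates 1 and 2.

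Monocytes kept for 1 day in macrophage differentiation medium (n = 12 and 12) had 2586 genes higher and 3572 lower than at day 0. The chemokine genes CCL22 and PPBP rose by 6.14 ± 0.44 (adjusted p = 1.98e-16) and 6.02 ± 0.52. The protease genes MMP9 and CTSL rose by 6.11 ± 0.48 and 5.18 ± 0.40, IL7R by 5.16 ± 0.37 and SCG5 by 5.11 ± 0.32. The purinergic receptor gene P2RY13 (-6.73 ± 0.44), RGS2 (-5.82 ± 0.37), TNFSF10 (-5.73 ± 0.32), CD1D (-5.34 ± 0.38) and, on HG-U133B, JAML (-5.93 ± 0.37) fell. Inflammatory and NF-kB genes rose at 17 of 21, with the chemokine CCL20 at 8.00 and the cytokines IL1A at 7.00 and IL6 at 6.25 (18 adjusted over the list alone; adjusted p = 2.03e-10, and adjusted p = 0.105 with an estimated correlation). Dendritic cell maturation genes rose at 17 of 21, with EBI3 at 7.53, LAMP3 at 6.18 and CD86 lower at -1.83 (17 rose and 1 fell adjusted over the list alone; adjusted p = 5.52e-09, and adjusted p = 0.105 with an estimated correlation). MHC class II genes fell at 8 of 10, with CD74 at -3.25 (8 adjusted over the list alone; adjusted p = 4.9e-05, and adjusted p = 0.105 with an estimated correlation). Monocyte genes fell at 10 of 14, with MNDA at -6.88 and FCN1 at -5.81 and AQP9 higher at 2.18 (1 rose and 10 fell adjusted over the list alone; adjusted p = 0.000152, and adjusted p = 0.147 with an estimated correlation). Macrophage genes rose at 13 of 25 and fell at 5 (CD163 at -3.23, LIPA at -2.81, MARCO at -2.69, FUCA1 at -2.17 and CTSK at -0.98), with SPP1 at 5.84 (14 rose and 5 fell adjusted over the list alone; adjusted p = 0.00577, and adjusted p = 0.315 with an estimated correlation). In 6 of the 12 day 1 samples the 3'/5' ratio of the ACTB control probes lay above the highest day 0 value of 1.96. Day 0 replicate 6 lay near the day 1 samples. Without the 3 day 1 samples of highest ratio 6122 genes changed, and 6325 changed without day 0 replicate 6.

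After 7 days (n = 12) 3212 genes were higher and 2885 lower than at day 0. The secreted glycoprotein gene CHI3L1 rose by 7.78 ± 0.44 (adjusted p = 2.96e-20), the transcription factor BHLHE41 by 7.21 ± 0.46 and AKR1C3 by 6.85 ± 0.58. The osteopontin gene SPP1 rose by 6.58 ± 0.49, GPNMB by 6.55 ± 0.41, TREM2 by 6.09 ± 0.32 and C1QC by 6.00 ± 0.32. The fractalkine receptor CX3CR1 fell by 7.71 ± 0.42, the complement regulator CFP by 6.62 ± 0.29, S100A12 by 6.33 ± 0.21, FOSB by 6.23 ± 0.38 and TRAF3IP3 by 5.92 ± 0.36. Macrophage genes rose at 24 of 25, with MRC1 at 5.67 (24 adjusted over the list alone; adjusted p = 1.25e-14 and 0.0127 with an estimated correlation). Immediate early genes fell at 10 of 11, with ATF3 higher at 3.05 (1 rose and 10 fell adjusted over the list alone; adjusted p = 3.42e-06 and 0.0437 with an estimated correlation). Monocyte genes fell at 13 of 14, with VCAN at -3.85 and AQP9 higher at 1.26 (1 rose and 13 fell adjusted over the list alone; adjusted p = 6.97e-06, and adjusted p = 0.056 with an estimated correlation). Interferon response genes fell at 19 of 23 (19 adjusted over the list alone; adjusted p = 2.44e-06, and adjusted p = 0.182 with an estimated correlation), with IFI44L at -3.81. Oxidative phosphorylation rose at 21 of 23 (22 adjusted over the list alone; adjusted p = 3.42e-06, and adjusted p = 0.056 with an estimated correlation). Lysosome genes rose at 19 of 28, with CTSD at 2.30 and with CTSS and PSAP lower at -0.52 and -0.39, the latter at 0.01 after quantile normalization (19 rose and 2 fell adjusted over the list alone; adjusted p = 6.93e-05, and adjusted p = 0.182 with an estimated correlation). Cholesterol synthesis genes rose at 10 of 13, with MSMO1 at 3.45 (10 adjusted over the list alone; adjusted p = 0.00013, and adjusted p = 0.056 with an estimated correlation).

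**Figure D5:**
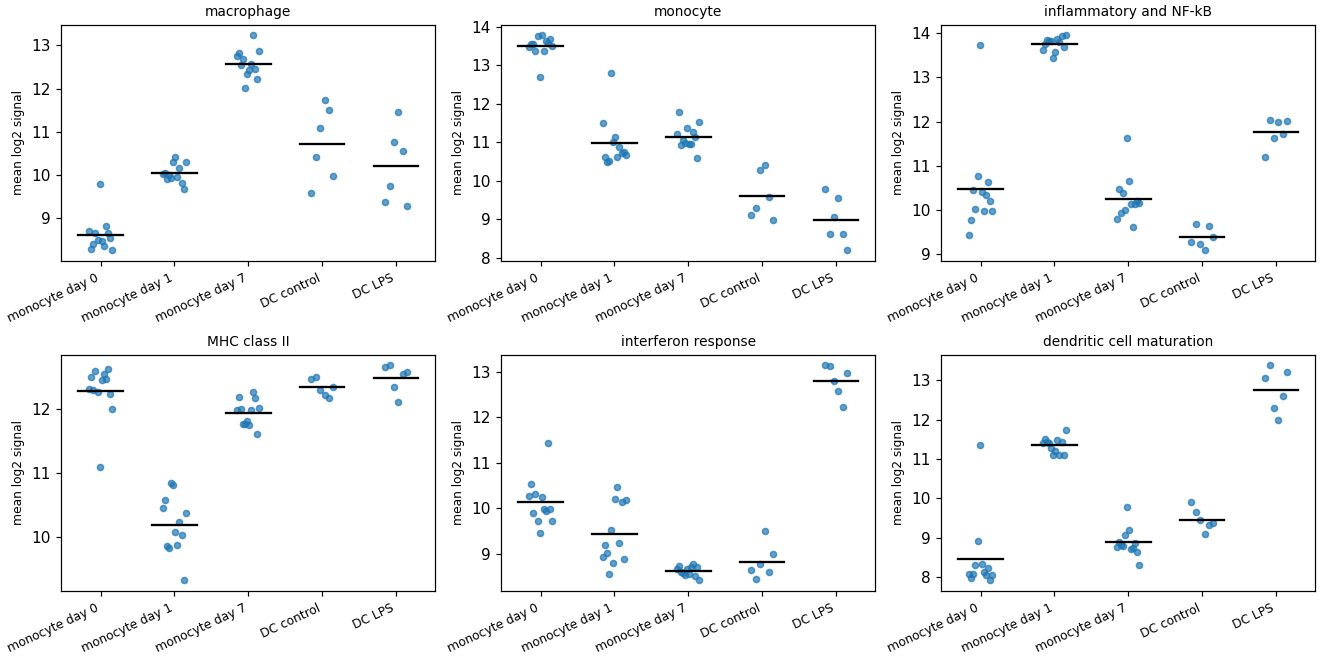
Mean log2 signal of 6 gene lists in each monocyte and dendritic cell sample, with points for samples and bars for group means. Macrophage genes rose at 24 of 25 by day 7, and all 23 interferon response genes rose after LPS.

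Between day 1 and day 7 the inflammatory and NF-kB list fell at 21 of 21 genes, with CCL20 at -8.49 ± 0.62 (adjusted p = 2.3e-16) and PTGS2, the inducible cyclooxygenase, at -5.80 (21 adjusted over the list alone; adjusted p = 4.61e-15 and 0.0345 with an estimated correlation). In all 3621 genes rose and 2546 fell. The scavenger receptor MARCO (6.49 ± 0.42), TREM2 (5.85 ± 0.32), the lipid carrier FABP4 (5.69 ± 0.48), C1QA (5.66 ± 0.33), MS4A4A (5.54 ± 0.53), VSIG4 (5.33 ± 0.29) and C1QC (6.79 ± 0.32) rose. EBI3 (-7.88 ± 0.58), SERPINB7 (-7.51 ± 0.67), CCL1 (-6.80 ± 0.67), IL36G (-6.79 ± 0.52), IL24 (-6.51 ± 0.50) and ACOD1 (-4.40 ± 0.37) fell. MHC class II genes rose at 7 of 10, with HLA-DPB1 at 3.68 (8 adjusted over the list alone; adjusted p = 0.000244, and adjusted p = 0.084 with an estimated correlation). Macrophage genes rose at 18 of 25, with APOE at 4.59 and CTSL lower (18 rose and 1 fell adjusted over the list alone; adjusted p = 5.22e-07, and adjusted p = 0.084 with an estimated correlation). Oxidative phosphorylation genes rose at 19 of 23 (21 adjusted over the list alone; adjusted p = 1.88e-08 and 0.0345 with an estimated correlation). Relative to day 0, both days raised 1530 genes and lowered 1715, and 757 moved in opposite directions, where independent lists would share 730.2 and 906. The correlation was 0.59 (simulated 0.50) with a covariance of 0.676 (simulated 0.022), 66.5% of all genes had the same sign (simulated 66.7%), and with the day 0 samples split 0.53 with 1213 and 1263 genes. Quantile normalization moved the median of all genes from 0.08 to -0.04.

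Dendritic cells exposed to LPS for 24 h (n = 6 and 6) had 1524 genes higher and 2370 lower than untreated dendritic cells. The tryptophan-degrading enzyme gene IDO1 rose by 7.41 ± 0.56 (adjusted p = 4.97e-15) and the interferon-induced genes IFI44L, ISG20 and IFI27 by 7.41 ± 0.56, 7.01 ± 0.41 and 6.93 ± 0.39. The cytokine subunit gene EBI3 rose by 7.25 ± 0.82 and the chemokine gene CXCL11 by 6.91 ± 0.54, with NEURL3 (5.26 ± 0.48) on HG-U133B. AIF1 fell by 5.95 ± 0.69, the lipoxygenase gene ALOX15 by 5.59 ± 0.57, MS4A6A by 5.43 ± 0.61, QPRT by 5.10 ± 0.42, the lectin gene CLEC10A by 5.06 ± 0.39 and S100B by 4.68 ± 0.34. All 23 interferon response genes rose, with RSAD2 at 5.84 (23 adjusted over the list alone; adjusted p = 4.59e-32 and 0.00325 with an estimated correlation). All 21 maturation genes rose, with the homing receptor CCR7 at 5.40 and the interleukin-12 subunit IL12B at 5.22 (21 adjusted over the list alone; adjusted p = 7.21e-18 and 0.0102 with an estimated correlation). Inflammatory and NF-kB genes rose at 17 of 21, with CCL20 at 6.10 (17 adjusted over the list alone; adjusted p = 1.46e-12 and 0.0395 with an estimated correlation). Genes of the dendritic cell list fell at 11 of 14, with CSF1R at -3.88 and CCL17 higher at 1.41 (1 rose and 11 fell adjusted over the list alone; adjusted p = 6.68e-05 and 0.0382 with an estimated correlation). Oxidative phosphorylation fell at 14 of 23, with ATP5PB at -1.27 and SDHA higher at 0.60, which did not pass with the numbered pairs as a block (1 rose and 15 fell adjusted over the list alone; adjusted p = 0.00607, and adjusted p = 0.268 with an estimated correlation).

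Untreated dendritic cells (n = 6) compared with day 0 monocytes (n = 12) had 2629 genes higher and 2015 lower. TREM2 was higher by 7.39 ± 0.39 (adjusted p = 9.45e-21), A2M by 6.47 ± 0.32, and CD1B by 6.40 ± 0.41. Also higher were ALOX15 by 6.28 ± 0.49, CCL22 and CCL17 by 6.23 ± 0.54 and 6.07 ± 0.35, C1QC by 7.02 ± 0.39 and the succinate receptor SUCNR1 by 5.14 ± 0.37. FCN1 (-7.64 ± 0.50), CX3CR1 (-7.64 ± 0.52), CFP (-7.63 ± 0.36), VNN2 (-6.63 ± 0.29), VCAN (-6.54 ± 0.41) and S100A12 (-6.33 ± 0.25) were lower. The dendritic cell list was higher at 12 of 14, with CD1E at 5.10 and CD1A at 4.60 (12 adjusted over the list alone; adjusted p = 4.16e-09 and 0.00305 with an estimated correlation). The monocyte list was lower at 14 of 14 (14 adjusted over the list alone; adjusted p = 1.62e-12 and 0.00305 with an estimated correlation). Immediate early genes were lower at 9 of 11, with FOS at -6.28 and ATF3 higher at 1.64 (1 higher and 10 lower adjusted over the list alone; adjusted p = 7.28e-09 and 0.00444 with an estimated correlation). Macrophage genes were higher at 19 of 25 and lower at 3 (19 and 3 adjusted over the list alone; adjusted p = 1.34e-05, and adjusted p = 0.137 with an estimated correlation). Of these FABP4 stood at 5.51 and CD163, MARCO and CTSK at -3.42, -2.32 and -0.56. Interferon response genes were lower at 19 of 23 (20 adjusted over the list alone; adjusted p = 5.64e-07, and adjusted p = 0.205 with an estimated correlation).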

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

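All tests of explanations in this part were chosen after the results were seen. A sample is listed where its gap to the nearest sample of its group, divided by the range of the group, exceeded Dixon's 95% critical value. This was checked in groups of 4 to 10 samples and held for 30 of 274 named genes in their groups and for 7 of 44 array measures. Chance marks about 1 in 20 groups. Each gap below is followed by the sample's log2 signal and that of the nearest sample, or by the array medians (linear signal) or ratios named.

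In untreated NK cells, replicate 3 was lowest in FGFBP2 (gap 0.954 of the range, 10.46 beside 14.12) and CLIC3 (0.899, 11.57 beside 12.99) and highest in SQLE (0.884, 10.68 beside 9.81). Replicate 2 was lowest in UHRF1 (0.937, 5.43 beside 8.37) and highest in EPHA4 (0.868, 11.85 beside 9.24), and replicate 4 highest in LTF (0.891, 14.28 beside 12.48). After interleukin-2, replicate 1 was lowest in OSM (0.716, 7.25 beside 8.54) and highest in CAMP (0.74, 7.41 beside 6.47) and DPEP2 (0.736, 7.86 beside 5.48). Replicate 4 was highest in DUSP1 (0.802, 10.86 beside 9.41) and MANF (0.825, 12.74 beside 12.2) and lowest in MCM2 (0.772, 12.03 beside 12.85) and DHCR7 (0.836, 8.76 beside 9.4). After interleukin-15, replicate 6 was highest in DPEP2 (0.784, 7.32 beside 5.61). On HG-U133A untreated replicate 3 correlated best with interleukin-2 replicate 4 (0.914 over genes, against 0.842 within its own group).

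In CD8+ T cells replicate 3 was lowest in CD4 (0.873, 6.67 beside 8.15) and highest in CRTAM (0.845, 11.82 beside 11.19). Of the naive B cell marks, replicate 6 held most. It was lowest in CD27 (0.705, 8.36 beside 9.51) and ERN1 (0.766, 9.29 beside 10.39) and highest in MZB1 (0.656, 8.62 beside 7.16), HSP90B1 (0.76, 8.64 beside 6.05), MANF (0.791, 9.48 beside 7.32) and GPR18 (0.747, 12.64 beside 11.6). Its array medians were lowest too, on HG-U133A (0.718, 369.8 beside 512.5) and HG-U133B (0.681, 169.8 beside 193.9). On HG-U133A it correlated best with IgM memory replicate 4 (0.928 over the brighter probe sets, against at most 0.855 within its group). Naive replicate 7 was highest in ZBTB32 (0.631, 6.88 beside 6.05), replicate 4 lowest in IL21R (0.699, 9.04 beside 10.03) and replicate 5 highest in AIM2 (0.671, 10.67 beside 9.64). IgG/IgA memory replicate 1 was highest in TNFRSF17 (0.85, 11.98 beside 9.64) and lowest in its HG-U133B median (0.852, 177.2 beside 202.5). In untreated dendritic cells replicate 6 was highest in IFI44L (0.648, 6.83 beside 5.66) and lowest in NEURL3 (0.702, 6.18 beside 6.61), replicate 5 lowest in IFI27 (0.858, 5.85 beside 7.24) and replicate 4 highest in RSAD2 (0.675, 8.51 beside 7.88).

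The 3'/5' signal ratio of control probes, a measure of RNA integrity and labelling, was highest for GAPDH in LPS dendritic cell replicate 2 (0.735, ratio 1.44 beside 1.08). For ACTB it was highest in interleukin-15 NK replicate 6 (0.684, 1.46 beside 1.07), naive B replicate 3 (0.81, 4.41 beside 1.81) and neutrophil replicate 1 (0.911, 8.81 beside 1.93). These control probes enter no comparison. Among day 1 monocytes the ACTB ratio reached 65.89 in replicate 7. With the ratio as a covariate 6129 genes changed between day 1 and day 0, against 6158.

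Genes of granulocyte granules stood high in untreated NK cells, with LTF at 12.86 ± 0.95 (SD) against 7.18 ± 0.36 in neutrophils. Mature neutrophils are argued against as the whole source. The lowest granule list mean of an untreated NK sample, 9.41, exceeded the highest of neutrophils, 9.00. Of the 10 genes, 5 lay above every neutrophil sample. Neutrophil genes like FPR1 (9.27 against 15.6) stayed lower. Yet 5 of 16 passed as higher in NK cells than the other lineages' mean, so some neutrophils stay open. Granulocyte precursors in the samples may be the source. Over the 15 NK samples a granule gene correlated with the others' mean at a median of 0.92. The highest of 1000 random gene sets gave 0.64. A change within NK cells under cytokine would also move these genes together and was not tested.

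The HG-U133B array of resting CD4+ T cell replicate 1 resembled activated cells. On a scale from 0 (unactivated memory cells) to 1 (activated) it lay at 0.71, against 0.02 and 0.04 for the other resting CD4+ arrays, and it correlated best with Th1 48 h replicate 1 (0.864 over genes, against 0.698 within its group). Activated cells in the sample are argued against by its HG-U133A array, at 0.01. A swap with an activated sample of the series is argued against because the lowest HG-U133B position of those samples was 0.55. A mislabelled array stays open as a candidate explanation, and no biological explanation was tested.

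Monocyte day 0 replicate 6 lay near the day 1 samples, at 0.78 on HG-U133A on a scale from 0 (day 0) to 1 (day 1), and at 0.73 on HG-U133B. It correlated best with day 1 replicate 5, at 0.973 on HG-U133A, where the highest of the 629 other pairs of monocyte samples gave 0.972, and at 0.936 on HG-U133B, where another pair reached 0.945. A swap with a day 1 sample is argued against, since the lowest day 1 position was 0.74, and RNA degradation by an ACTB ratio of 1.59, within the 1.01 to 1.96 of the other day 0 samples. A mislabelled sample could explain the HG-U133A position but not so plainly that on HG-U133B, which lay below the lowest day 1 value of 0.8, so it stays open. No biological explanation was tested.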

How the results depend on the processing

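The alternatives chosen after the data were seen are named above, under the processing. The other alternatives were planned. Over settings other than leaving out a sample, the values of named genes kept their direction and side of the threshold in 4538 of 4711 cases, fell below it in 171, and in 2 went to 0 (TNFSF14) or changed sign (PSAP). For gene lists this held in 1102 of 1109, with 5 no longer passing and 2 newly passing. Leaving out a sample left 2696 of 2833 gene values and 371 of 382 list values as they were, with 137 and 9 no longer passing, 1 list newly passing and 1 reversed. The replicate block accounted for 56 of the 171 gene values that fell below the threshold and the fit on the compared groups for 30. No leave-out changed the direction of a named gene.

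The direction of a list was read from the set test, not from its median. Without untreated NK replicate 3 the interferon response list after interleukin-2 had a median of 0.62 (adjusted p = 0.0328, with 0.0328 to 0.913 over its alternatives), against -0.11 with all samples, and without interleukin-2 replicate 4 it was -0.66 (adjusted p = 0.0346). Between the cytokines the median of the granulocyte precursor list went from 0.52 to -0.04 with the replicate block, although the set test kept its direction. With values floored at the chip median TNFSF14 differed by 0 between CD8+ and CD4+ T cells (adjusted p = 1, from 0.0142 to 1), a call lost because flooring removes signal below the median. After quantile normalization PSAP stood at 0.01 in day 7 monocytes (adjusted p = 0.872, from 4e-05 to 0.872), and the cause was not tested.

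With the replicate number as a block (replicate block), fitted on the compared groups alone, these counts moved by more than 1.5 times: 33 genes for interleukin-2 in NK cells (960 without the block), 168 for interleukin-15 (1259), 10 for Th2 against Th1 at 48 h (23), 93 for 48 h against 12 h (734), 184 for unactivated memory against resting CD4+ T cells (622), 3 for CD8+ against CD4+ T cells (279), 465 for IgM memory against naive B cells (279) and 7 between the memory B classes (3). In none of these did the numbers pair the samples throughout. From 12 h to 48 h they paired the Th2 but not the Th1 samples, and with the Th2 samples alone paired 890 genes changed. Samples without a like-numbered partner, such as naive B replicate 6, may also have moved these counts, which was not tested. In the 3 comparisons that were paired, the paired fit gave 0 genes between the cytokines (0), 5025 for activated memory T cells (3691) and 4319 for LPS (3894). In these the block and the fit on the compared groups alone both brought the memory T list past the threshold in activated cells (adjusted p = 0.028 and 0.0219, from 0.0219 to 0.237 over its alternatives), and SDHA passed under neither after LPS. The block, but not the fit on the compared groups, ended the granulocyte precursor call between the cytokines (adjusted p = 0.872, from 1.23e-05 to 0.872), which the mean of all probe sets and the deposited scaling ended too (adjusted p = 0.0709 and 0.106). The former also ended the oxidative phosphorylation call there (adjusted p = 0.0709, from 0.000284 to 0.0719), and flooring the Th1 list call in Th2 cells at 48 h (adjusted p = 0.0723, from 0.00309 to 0.163).

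The fit on the compared groups alone, with fewer samples, gave 2586 genes for Th2 at 48 h against resting cells (3935), 0 for Th2 against Th1 at 12 h (7) and 6 at 48 h (23). It also gave 287 for 48 h against 12 h, 106 for memory against resting CD4+ T cells, 47 for CD8+ against CD4+, and 190 and 117 for IgG/IgA (405) and IgM memory B cells. The fit over all 22 groups gave 16 at 12 h and 40 at 48 h for Th2 against Th1, 369 for 48 h against 12 h, 458 for IgM memory B cells and 18 between the memory classes. Under the deposited scaling the counts were 611 for interleukin-2, 4 and 59 for Th2 against Th1, 402 for 48 h against 12 h, 264 for memory CD4+ T cells, 63 for CD8+, 189 for IgG/IgA and 121 for IgM memory. Flooring gave 38 and 37 for Th2 against Th1, 567 for CD8+ and 9 between the memory classes. A pseudocount of 1 gave 14 for Th2 against Th1 at 48 h, and one of 64 gave 7 between the memory classes and 93 B cell lineage genes (158). Quantile normalization gave 7, 1792 for marrow plasma cells (3392) and 105 B cell lineage genes. Without a trend IgG/IgA and IgM memory gave 269 and 172. Without the HG-U133B array of resting CD4+ replicate 1, CD8+ cells gave 502. Without naive B replicate 6, IgG/IgA memory gave 882, IgM memory 684 and marrow plasma cells 4091, within 1.5 times, while the named genes and lists kept their calls. A margin of 2 log2 units, a stricter rule, left 24 T cell, 54 NK, 22 B cell, 78 plasma cell, 26 monocyte, 119 dendritic cell and 71 neutrophil genes. Apart from the fewer samples and the stricter rule, the cause was not tested.

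Leaving out in turn each sample of the groups of 2 to 5 gave these ranges, with every such sample that moved a count by more than 1.5 times. Samples of larger groups, such as naive B cells and interleukin-15 NK cells, were not left out, so the ranges do not cover them. Interleukin-2 gave 546 to 1454 (untreated replicates 1, 2 and 3: 587, 546 and 1454) and interleukin-15 703 to 1632 (untreated 1 and 2: 807 and 703). Th2 against Th1 gave 1 to 8 at 12 h (Th2 1 and 2: 2 and 3, Th1 2: 1) and 8 to 40 at 48 h (Th2 1 to 3: 15, 37 and 8, Th1 1 to 3: 13, 40 and 14). The range was 236 to 902 for 48 h against 12 h (Th1 48 h 3: 439, Th1 12 h 1: 236, Th2 12 h 2: 385). It was 258 to 900 for memory against resting CD4+ T cells (memory 1 to 3: 393, 258 and 357, resting 2: 351) and 146 to 571 for CD8+ (CD8+ 2 to 4: 161, 178 and 163, CD4+ 1 and 2: 571 and 146). IgG/IgA memory gave 180 to 368 (memory 1 and 2: 180 and 245), IgM memory 124 to 305 (memory 1, 2 and 4: 136, 124 and 136), and the memory classes 2 to 7 (IgG/IgA 1 and 3: 5 and 7, IgM 1: 7). Marrow plasma cells gave 1964 to 3014 (blood 1 and 2: 2167 and 1964). Counts within 1.5 times throughout were 3373 to 4278 for Th1 and 2767 to 4072 for Th2 at 48 h, 2734 to 3339 for activated memory T cells and 6052 to 6725 for blood plasma cells. Lineage counts stayed so too, and the cytokines differed in 0 genes in all 5 interleukin-2 leave-outs. At 12 h leaving out a Th1 sample leaves 1, which is assumed to vary like the other groups.

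Comparisons of monocytes and dendritic cells stayed within 1.5 times under every setting, the covariate and exclusions included, from 5684 to 6672 genes for day 1. Signal near background limits dim genes in part: with values floored at the chip median 21 of 337 named gene values no longer passed and TNFSF14 had no difference left. With no filter, which also adds genes to the adjustment, 7 of 380 no longer passed. Lineage counts were not run with flooring, the block or other sets of groups. With the mean of all probe sets 375 of the 380 named gene values could be given, since CD4 in CD8+ against CD4+ T cells, HBEGF after interleukin-15, PHLDA2 at 48 h against 12 h, BAIAP3 in IgG/IgA memory B cells and EVI5 in activated memory T cells no longer met the filter.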

Other observations

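The splits of samples described here were tested after the comparisons had been seen. Other splits of the same samples into groups of the same sizes were drawn to ask whether chance can be excluded. It can for interleukin-2 (960 genes, highest other split 250) and interleukin-15 (1259, 817) in NK cells, and 48 h against 12 h (734, 567, the latter also the highest other of the 80 splits that part every Th2 pair). The same holds for blood plasma cells against naive B cells (7490, 4754), day 1 (6158, 3775) and day 7 (6097, 2548) against day 0, day 7 against day 1 (6167, 2176), and dendritic cells against monocytes (4644, 3211). For LPS in dendritic cells it can as well (3894, 2866), where the 32 splits that exchange members of numbered pairs gave at most 2676. For IgG/IgA (405, 769) and IgM memory B cells (279, 2019) against naive cells few splits reached the real count. They numbered 2 and 3 of 100, with the real split included. Since other splits called more genes than the real one, the counts alone do not exclude chance. For IgM cells a split called several times the real count, which points to a structure of these samples other than their groups.

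Chance cannot be excluded between the memory B classes, where 4 of 35 splits reached the real 3 genes (highest 11). Between the cytokines the real count is 0, which all 100 splits reach whatever the data hold, so they decide nothing (highest other 8, and 0 over 16 splits of the numbered pairs). With 3 samples against 3 the splits are too few to tell: the real and highest other counts were 4183 and 273 for Th1 and 3935 and 556 for Th2 at 48 h against resting cells, 23 and 6 for Th2 against Th1 at 48 h, 3691 and 1 for activated memory T cells, and 622 and 48 for unactivated memory against resting cells. For lineage genes the splits mixed samples of all lineages, so they ask only whether the cell types separate at all. The real count exceeded every other split for T cells (103, highest other 2), B cells (158, 39), plasma cells (311, 165), monocytes (106, 31), dendritic cells (396, 8) and neutrophils (322, 97). For NK cells (181, 984) 2 of 100 splits reached the real count, with the real split included. There, 1 other split called several times the real count, so the count alone does not exclude chance. This again points to a structure of the samples.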
